A study of Mus musculus with 12 samples.

How the data were processed

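Total RNA of activated mouse CD4+ CD25- T cells was extracted with Trizol and purified on columns, labelled with biotin and hybridised to Affymetrix arrays, 1 array per sample, per the labels' protocols. Deposited values were probe set intensity on a linear scale, 1 column for each of 12 arrays, and the authors made them with RMA, per the submitters' processing notes. RMA corrects background, normalizes quantiles between arrays and fits each probe set's probes. Its version, the scan dates and the batches are not given in the sources used here. Quantile normalization sets the arrays to near equal distributions, so a shift of all transcripts between groups would not appear in these values. No detection calls were used, so transcripts near background were not told apart from absent ones, and the fold change of a dim gene can be understated. Array medians lay between 6.60 and 6.68 on the log2 scale, and Cth (4.58 and 4.89 with MAZ1310) and Gpt2 (5.27 and 5.39) lay below them.

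Here log2 of the intensity was taken before any test, as the design fixed before the data were examined had provided for linear values. Of 45101 probe sets, 64 were array controls, 34945 carried a single gene symbol, 932 carried several and 9160 were not in the annotation table used. Of 34958 probe sets with a single symbol, controls counted, 34754 had an Entrez identifier in a current gene table, and 0 of them changed symbol. Each gene was represented by the probe set with the highest mean over the 12 arrays, which gave 18193 genes, 9010 of them with more than 1 probe set. Probe sets of 1 gene can disagree, as those of Fdft1 did at 6 h. No genome was used, so genes are named by symbol without coordinates. List genes without a single-symbol probe set in the table used were not analysed here.

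Groups were compound and time, with 3 arrays each. They were described as biological replicates with no word on which animals or cultures they came from, so p-values measure the spread between these samples. A model with 4 group means was fitted to all 12 arrays with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes), so that the groups shared 1 estimate of spread. The contrasts were HF against MAZ1310 at 3 h and at 6 h, the difference of these effects, and 6 h against 3 h within each compound. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes, and a 2-fold change was an absolute log2 fold change of at least 1. Intervals are 95% intervals from the moderated test. Adjusted p-values of genes and lists in the text are from limma unless a permutation test is named.

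The comparisons, thresholds, rule for named genes, 32 gene lists and most alternatives were fixed before the data were examined. Named genes were the 10 largest increases and decreases per HF contrast among called genes whose arrays did not overlap between groups. For the genes called at both times they were the 10 of largest mean size, and for the other contrasts the 6 largest in each direction. A fixed set of genes was always named where measured, among them Asns, Atf4, Ddit3, Chac1, Trib3, Il17a, Rora, Il2, Smad7 and Hspa5, with up to 4 called members of each list, or the 2 largest changes of a list with none. Symbols that are only clone names kept their rank unnamed. Lists were tested against other genes with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 32 lists, and again with an estimated correlation and with fry. Counts adjusted over the list alone are given where they differ from the counts over all genes.

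The lists were written from general knowledge and not from these samples, but HF was already known to act on the amino acid response. They covered ATF4 targets, amino acid synthesis and transport, tRNA synthetases, endoplasmic reticulum chaperones, eIF2a kinases, translation factors, ribosomal proteins, ribosome biogenesis, mTORC1 regulators, autophagy, glycolysis, sterol synthesis, p53, NRF2, heat shock and interferon genes. T cell lists covered Th1, Th2, Th17, Treg, naive, T cell receptor, TGFb, IL-6 and cell cycle genes. Marker lists covered T cells, B cells, myeloid cells, CD8 T or NK cells, MHC class II presenting cells and erythroid cells. The 3' to 5' difference of the actin and Gapdh control probe sets served as a sign of RNA quality.

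Replicate numbers come from the labels, which do not say what they share. Deviations from the group means of equally numbered HF and MAZ1310 arrays correlated at 0.242 to 0.381 at 3 h and 0.287 to 0.391 at 6 h. Between times they correlated at 0.322 to 0.502 for HF and 0.0289 to 0.252 for MAZ1310, where 2 of 3 pairs passed 0.1. Numbers were therefore taken to pair HF with MAZ1310 arrays, and a replicate block was fitted as an alternative. The main fit stayed the planned one without the block, so its counts, SEs and intervals do not use this pairing.

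Other alternatives were cyclic loess, a filter on dim genes, the mean of a gene's probe sets, every probe set on its own, leaving out probe sets with _s, _x or _a suffixes, eBayes with trend and robust settings, array weights, only the compared groups, an adjusted p under 0.01 and leaving out each array. After the data were seen, the actin difference as a covariate, leaving out the arrays numbered 2, and the block with the covariate were added. The model was tested on simulated data for the 3 h comparison over 18193 genes. It called 42 of 67 genes changed by 0.5 on the log2 scale (62.7%), 63 of 67 changed by 1 (94.0%) and 65 of 66 changed by 2 (98.5%), with 5 unchanged genes called. The simulated noise was independent between genes and arrays, without effects of replicate number or RNA quality. These rates therefore need not hold for the real arrays. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.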

Results

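Expression was measured in mouse CD4+ CD25- T cells, the helper T cells left when cells bearing the IL-2 receptor alpha chain are set aside. The cells had been activated through CD3 and CD28 and cultured with TGFb and IL-6, the cytokine pair that starts Th17 differentiation. They received 10 nM halofuginone (HF), a halogenated derivative of the plant alkaloid febrifugine, or 10 nM of MAZ1310, described by the submitters as an inactive derivative of HF. RNA was taken after 3 h or 6 h, which gave 4 groups of 3 arrays, described as biological replicates, or 12 arrays in all. The array medians lay between 97.3 and 102 intensity units. After 1 probe set per gene was kept, 18193 genes were compared. Pairs of arrays within a group correlated at r = 0.992 to 0.997 across these genes. Changes are log2 fold changes ± SE, with adjusted p from limma, 3 arrays a group. In the comparisons at 3 h and at 6 h, rose and fell mean higher and lower with HF than with MAZ1310, not a change over time. Precision is limited by that number of arrays.

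The comparison at 3 h asked which transcripts differed early between HF and its inactive derivative. Genes of the amino acid response, which the transcription factor ATF4 drives when amino acids or charged tRNAs run short, rose with HF. Gpt2, a mitochondrial alanine transaminase, rose by 3.21 ± 0.11 (adjusted p = 2.1e-10) from a dim signal of 32.9 to 41.8 intensity units with MAZ1310, so the size of the change is uncertain. Trib3, a pseudokinase that restrains ATF4 signalling, rose by 2.87 ± 0.23, and Eif4ebp1, a repressor of cap-dependent translation, by 2.79 ± 0.13. Chac1, which degrades glutathione, rose by 2.65 ± 0.14, and Ddit3, the stress transcription factor CHOP, by 2.49 ± 0.12. Atf4 itself rose by 0.47 ± 0.08 (adjusted p = 0.0022), a call lost without the 4 arrays numbered 2, with fewer arrays at a similar size (0.44, adjusted p = 0.0644), and with the replicate block and actin difference described further on (0.35, adjusted p = 0.275). Transcripts of heat shock proteins and of cholesterol synthesis fell.

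In all, 1726 genes differed at 3 h, 514 higher and 1212 lower with HF, and 96 of them changed at least 2-fold, 54 higher and 42 lower. This 2-fold split turned to 56 higher and 68 lower without MAZ1310 replicate 1 at 3 h, and to 50 and 52 without HF replicate 3 at 3 h. After cyclic loess between arrays the split was 723 higher and 1085 lower. With the replicate block 2428 genes differed, 777 higher and 1651 lower. For 22.8% of genes all HF arrays lay on one side of all MAZ1310 arrays, where chance gives 10%. Other large increases were in Pck2, a mitochondrial phosphoenolpyruvate carboxykinase (2.29 ± 0.11), Cebpb, a stress-linked transcription factor (1.97 ± 0.11), and Pdcd1lg2, the immune checkpoint ligand PD-L2 (1.71 ± 0.13). The serine synthesis enzymes Psph and Phgdh rose by 1.83 ± 0.16 and 1.76 ± 0.10. The strongest decreases were in the thiamine transporter gene Slc19a2 (-2.52 ± 0.16), the Hsp70 gene Hspa1b (-1.86 ± 0.29), the p53 target Ccng1 (-1.71 ± 0.11) and the neurofilament gene Nefh (-1.69 ± 0.22). Sbk1 (-1.59 ± 0.13), the zinc importer gene Slc39a10 (-1.47 ± 0.10), Ddias (-1.37 ± 0.17) and Atp23 (-1.33 ± 0.12) also fell.

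Of 23 measured genes in the list of ATF4 and its targets, 15 were higher and 1 lower at 3 h, and 16 higher and 1 lower when adjusted over the list alone. The list shifted upward against other genes by limma's camera test (median 0.62, adjusted p = 1.5e-19, and adjusted p = 0.000239 with an estimated correlation). Of 20 enzymes of amino acid synthesis, 11 were higher and 3 lower (13 and 4 adjusted over the list alone), among them Asns, asparagine synthetase, at 1.63 ± 0.17. Their camera p was 9.5e-09, and adjusted p = 0.0945 with an estimated correlation. Among 19 amino acid transporters, 8 were higher and 2 lower (9 and 4 adjusted over the list alone; camera adjusted p = 3.1e-05, and adjusted p = 0.037 with an estimated correlation). Slc6a9, a glycine transporter, rose by 1.29 ± 0.10, Slc7a3, a cationic amino acid transporter, by 1.01 ± 0.17 and Slc7a5, the light subunit of LAT1, by 0.92 ± 0.09. Among 19 aminoacyl tRNA synthetases, 10 were higher and 0 lower (12 and 2 adjusted over the list alone), with Aars at 1.43 ± 0.10, Lars at 1.19 ± 0.10 and Cars at 1.15 ± 0.13. The synthetase shift had a camera adjusted p of 1e-07, and adjusted p = 0.322 with an estimated correlation.

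Heat shock genes fell at 3 h: 11 of 14 were lower and 0 higher (the same counts adjusted over the list alone), including the chaperone genes Hsph1 (-1.58 ± 0.12), Hspa1a (-1.24 ± 0.22) and Bag3 (-1.19 ± 0.12). The median was -0.48 (camera adjusted p = 6.4e-13, and adjusted p = 0.037 with an estimated correlation). Of 18 sterol synthesis genes, 13 were lower and 0 higher (14 lower adjusted over the list alone; median -0.58, camera adjusted p = 5.5e-15, and adjusted p = 0.037 with an estimated correlation). Idi1, an isopentenyl diphosphate isomerase, fell by 1.26 ± 0.14, and Sqle, squalene epoxidase, by 1.25 ± 0.09. Of 16 p53 targets 7 were lower (2 higher and 10 lower adjusted over the list alone), with Zmat3 at -1.08 ± 0.14 and Ei24 at -0.97 ± 0.10. That list had adjusted p = 4.3e-07, and adjusted p = 0.0945 with an estimated correlation. Of 17 glycolysis and hypoxia genes 9 were lower and 1 higher (10 and 1 adjusted over the list alone; adjusted p = 0.00011, and adjusted p = 0.201 with an estimated correlation). The member that rose was Vegfa, the endothelial growth factor gene (1.70 ± 0.09), while Tpi1, triose phosphate isomerase, fell by 0.77 ± 0.11. Of 14 NRF2 targets 6 were lower (adjusted p = 0.00038, and adjusted p = 0.212 with an estimated correlation), with glutathione reductase, Gsr, at -1.01 ± 0.12. The NRF2 call was lost without probe sets that can detect several transcripts (adjusted p = 0.0771). Of 20 endoplasmic reticulum chaperone genes 7 were lower and 1 higher (8 and 1 adjusted over the list alone; adjusted p = 0.00017, and adjusted p = 0.0945 with an estimated correlation). The protein disulfide isomerase gene Pdia3 fell by 0.81 ± 0.10, Herpud1, of endoplasmic reticulum associated degradation, rose by 1.28 ± 0.10, and the call was lost with the replicate block and the actin covariate together (adjusted p = 0.14).

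**Figure D1:**
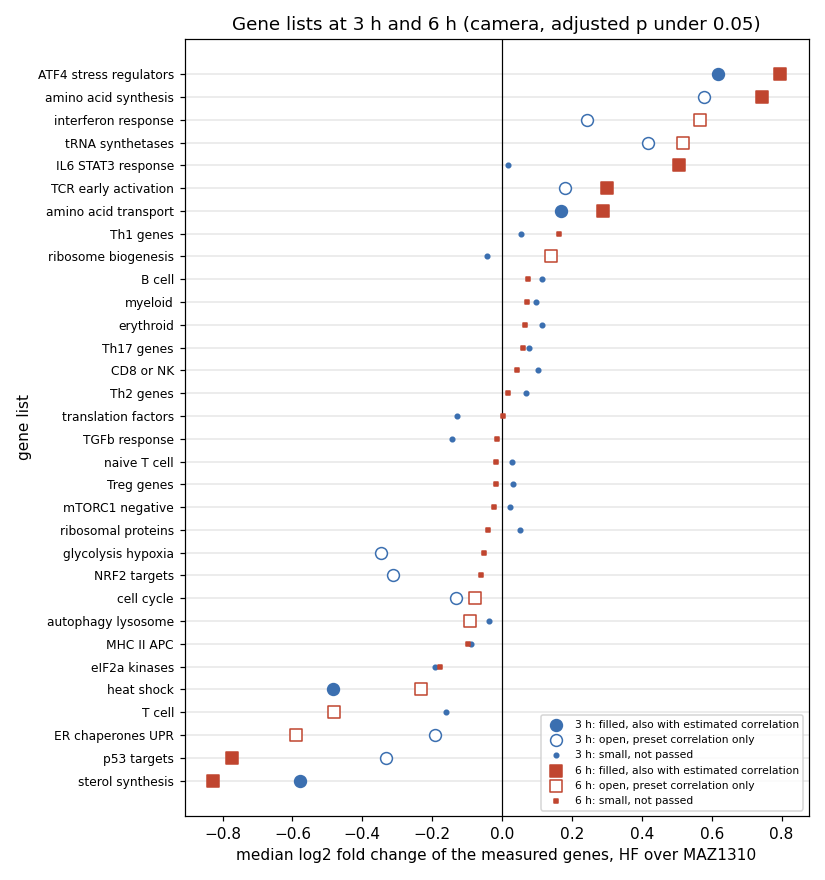
Median log2 fold change of HF over MAZ1310 (horizontal axis) for each of 32 gene lists (vertical axis) at 3 h (circles) and 6 h (squares). Filled symbols passed camera with the preset and the estimated correlation, open symbols with the preset alone and small symbols with neither; the ATF4 list stood at 0.62 and 0.80 and the sterol list at -0.58 and -0.83.

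Among T cell lists at 3 h, early T cell receptor response genes were higher in 10 of 29 and lower in 1 (12 and 2 adjusted over the list alone; adjusted p = 0.00038, and adjusted p = 0.0945 with an estimated correlation). Zfp36, which destabilises cytokine mRNAs, rose by 0.79 ± 0.12 and the immediate early gene Egr1 by 0.66 ± 0.11. Interferon response genes were higher in 5 of 21 (6 adjusted over the list alone; adjusted p = 0.00034, and adjusted p = 0.445 with an estimated correlation), led by the transcription factor gene Irf1 (1.04 ± 0.11). Cell cycle genes were lower in 7 of 28 (8 adjusted over the list alone; adjusted p = 0.00038, and adjusted p = 0.377 with an estimated correlation), with Mcm6 of the replicative helicase at -0.78 ± 0.12 and Cdk4 at -0.78 ± 0.12. That call was lost without MAZ1310 replicate 3 at 3 h (adjusted p = 0.052).

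Lists of T helper programs did not pass at 3 h. The Th17 list had 1 of 14 genes higher, Batf (0.49 ± 0.10), and 1 lower (adjusted p = 0.63). The Th1 list had 1 of 12 higher, the lineage factor gene Tbx21 (0.60 ± 0.11), and 2 lower (2 and 2 adjusted over the list alone; adjusted p = 0.81). The Th2 list, whose median and mean lay above 0 while its test pointed down, had 1 of 10 lower (Il4ra, -0.56 ± 0.09; adjusted p = 0.87). The Treg list had 1 of 11 higher (Ikzf4, 0.57 ± 0.09; 2 adjusted over the list alone; adjusted p = 0.26). TGFb response genes were higher in 1 of 18 and lower in 3 (adjusted p = 0.066), with Id1 at -0.57 ± 0.11, and IL-6 and STAT3 response genes were higher in 3 of 15 (adjusted p = 0.078), with the receptor gene Il6ra at 0.94 ± 0.17. Naive T cell genes were higher in 1 of 16 (Btg2, 0.74 ± 0.12; adjusted p = 0.87). Il17a, the Th17 cytokine gene, differed by 0.21 ± 0.34 (95% interval -0.50 to 0.93, adjusted p = 0.77). HF was the higher in 3 of 3 pairs of equal number, by 0.03 to 0.46, and with the replicate block the interval was -0.08 to 0.51 (adjusted p = 0.36). The intervals were -0.22 to 0.59 for Rora, a Th17 nuclear receptor, -0.34 to 0.11 for Il2, -0.33 to 0.11 for Smad7, an inhibitor of TGFb signalling, and -0.14 to 0.18 for the chaperone gene Hspa5. Il17f was not analysed here.

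Translation and growth lists did not pass camera at 3 h. Ribosome biogenesis genes had 0 of 25 called by limma, with 6 at an unadjusted p under 0.05 (adjusted p = 0.3) and Wdr12 called with the replicate block (-0.36, adjusted p = 0.0166), and ribosomal protein genes had 1 of 23 higher (adjusted p = 0.25). Translation factors were higher in 2 of 21 and lower in 3 (adjusted p = 0.076), with Eif2b4, an eIF2B subunit, at -0.81 ± 0.10. The list of negative mTORC1 regulators had 3 of 15 genes higher and 1 lower (3 and 3 adjusted over the list alone, adjusted p = 0.21). The higher ones were Eif4ebp1, Ddit4 (1.35 ± 0.11) and Sesn2 (1.12 ± 0.09), all known to respond to ATF4. Of these, Eif4ebp1 acts downstream of mTORC1 and is not one of its regulators. Genes of the eIF2a kinases and phosphatases were higher in 2 of 9 and lower in 3 (2 and 4 adjusted over the list alone; adjusted p = 0.41). Of the lower ones, Eif2ak4 turned from -0.46 to 0.20 without suffixed probe sets (adjusted p = 0.434). Autophagy and lysosome genes were lower in 4 of 19 (5 adjusted over the list alone; adjusted p = 0.12), among them Gabarapl1 (-0.61 ± 0.14).

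Of the marker lists of other cells at 3 h, 0 of 51 genes of B cells, myeloid cells, CD8 T or NK cells, MHC class II presenting cells and erythroid cells were called by limma, and 3 had an unadjusted p under 0.05. With the replicate block only the 2 largest changes of each of these lists were looked up. Of these, limma called Mpeg1 (-0.40, adjusted p = 0.0196), Prf1 (-0.34, 0.0314) and Cd74 (-0.32, 0.0412) lower and Ngp (0.30, 0.0145) higher. Of 12 T cell markers, 1 was lower (median -0.16, adjusted p = 0.066). The actin 3' to 5' signal difference, a sign of RNA quality in which higher values go with degraded RNA, was 1.03 ± 0.220 (SD, n = 3) with MAZ1310 and 1.25 ± 0.279 with HF. The difference was higher with HF in 3 of 3 pairs of equal replicate number, by 0.172 to 0.302. An exact permutation test over all arrays of that time, which does not use the pairs, gave p = 0.5 (two-sided, smallest possible 0.1). The Gapdh difference was 0.01 with MAZ1310 and 0.29 with HF (exact permutation p = 0.1). With the replicate block and the actin difference in the fit together, 419 genes differed, 185 higher and 234 lower. Without the 4 arrays numbered 2, which have the highest actin difference of each group, 657 genes differed.

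At 6 h the comparison asked what had followed by the later time. Among amino acid response genes Trib3 rose by 4.28 ± 0.23, Gpt2 by 4.06 ± 0.11 and Cth, the cysteine-forming enzyme cystathionine gamma-lyase, by 4.01 ± 0.20 (adjusted p = 4.9e-09). Atf5, a transcription factor downstream of ATF4, rose by 3.14 ± 0.16, Chac1 by 3.09 ± 0.14 and Cebpb by 3.01 ± 0.11. Interferon-inducible GTPase genes rose too, Gbp7 by 3.08 ± 0.19 and Gbp8 by 2.96 ± 0.20. Genes of p53 signalling fell.

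In all, 3085 genes differed at 6 h, 949 higher and 2136 lower, and 291 changed at least 2-fold, 114 higher and 177 lower. With the replicate block 3714 genes differed, 1218 higher and 2496 lower. For 36.8% of genes the HF and MAZ1310 arrays did not overlap (chance 10%). Pck2 rose by 2.89 ± 0.11 and Slc14a1, a urea transporter gene, by 2.72 ± 0.16. The strongest decreases were in the spindle gene Psrc1 (-2.92 ± 0.21), Ddias (-2.65 ± 0.17), Sh2d1a, the T cell signalling adaptor SAP (-2.25 ± 0.23), and Ccng1 (-2.20 ± 0.11). Gcdh, glutaryl-CoA dehydrogenase (-1.99 ± 0.14), the nucleoporin gene Aaas (-1.88 ± 0.14), Gtse1 (-1.82 ± 0.10) and the lysophosphatidylserine receptor gene Gpr174 (-1.81 ± 0.22) also fell. Laptm5, a lysosomal membrane protein gene, stood at -1.96 ± 0.12 on its brightest probe set and at 0.20 (adjusted p = 0.11) on the brightest without an _s, _x or _a suffix, which mark probe sets that can detect several transcripts.

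**Figure D2:**
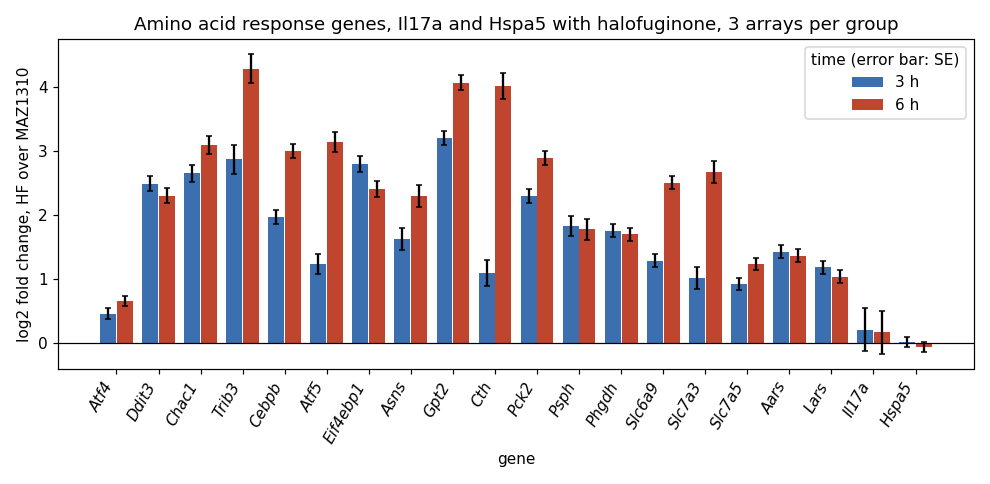
Log2 fold change of HF over MAZ1310 (vertical axis, bars from 0, error bars SE, 3 arrays per group) for 18 amino acid response genes, Il17a and Hspa5 (horizontal axis) at 3 h and 6 h. Gpt2 reached 3.21 and 4.06 and Cth 1.10 and 4.01, while the bars of Il17a, 0.21 and 0.17, were shorter than their error bars of 0.34.

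Of the ATF4 list, 15 of 23 genes were higher and 2 lower at 6 h (median 0.80, camera adjusted p = 1.5e-16, and adjusted p = 0.000446 with an estimated correlation). Atf4 rose by 0.66 ± 0.08 and Ddit3 by 2.30 ± 0.12. Of the 20 amino acid synthesis enzymes, 14 were higher and 2 lower (adjusted p = 1e-11, and adjusted p = 0.0375 with an estimated correlation), with Asns at 2.29 ± 0.17. Of 19 amino acid transporters, 10 were higher and 1 lower (10 and 3 adjusted over the list alone; adjusted p = 3.3e-08, and adjusted p = 0.0169 with an estimated correlation), with Slc7a3 at 2.67 ± 0.17 and Slc6a9 at 2.50 ± 0.10. Of 19 tRNA synthetases, 11 were higher and 1 lower (13 and 1 adjusted over the list alone; adjusted p = 5.3e-09, and adjusted p = 0.258 with an estimated correlation), with Aars at 1.37 ± 0.10.

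Sterol synthesis genes were lower in 13 of 18 at 6 h (15 adjusted over the list alone; median -0.83, adjusted p = 1.2e-14, and adjusted p = 0.029 with an estimated correlation), with Idi1 at -1.60 ± 0.14 and Fdps, farnesyl diphosphate synthase, at -1.28 ± 0.11. The p53 targets were lower in 11 of 16 (11 lower and 1 higher adjusted over the list alone; median -0.77, adjusted p = 1.2e-10, and adjusted p = 0.0375 with an estimated correlation), with Ei24 at -1.80 ± 0.10 and Phlda3 at -1.65 ± 0.11. Endoplasmic reticulum chaperone genes were lower in 12 of 20 and higher in 3 (13 and 3 adjusted over the list alone; median -0.59, adjusted p = 5.1e-05, and adjusted p = 0.0747 with an estimated correlation). Pdia3 fell by 1.65 ± 0.10 and Pdia4 by 1.41 ± 0.10, Herpud1 rose by 1.41 ± 0.10, and Hspa5 stood at -0.05 ± 0.07 (95% interval -0.21 to 0.11). Heat shock genes were lower in 4 of 14 (6 adjusted over the list alone; median -0.23, adjusted p = 0.0036, and adjusted p = 0.297 with an estimated correlation), with Hsph1 at -0.65 ± 0.12. Cell cycle genes were lower in 9 of 28 (10 adjusted over the list alone; adjusted p = 0.0093, and adjusted p = 0.582 with an estimated correlation), with the helicase gene Mcm5 at -0.83 ± 0.08 and the cyclin gene Ccnd3 at -0.73 ± 0.07.

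IL-6 and STAT3 response genes were higher with HF at 6 h in 10 of 15 and lower in 0 (median 0.51, adjusted p = 2.5e-07, and adjusted p = 0.029 with an estimated correlation). Fos rose by 0.98 ± 0.14, Junb by 0.85 ± 0.09, Socs3, a feedback inhibitor of STAT3, by 0.85 ± 0.16 and the receptor chain gene Il6st by 0.84 ± 0.09. Early T cell receptor response genes were higher in 15 of 29 and lower in 2 (adjusted p = 4.6e-07, and adjusted p = 0.029 with an estimated correlation), with Egr1 at 1.13 ± 0.11. Interferon response genes were higher in 11 of 21 (13 adjusted over the list alone; median 0.57, adjusted p = 6.7e-09, and adjusted p = 0.231 with an estimated correlation). The interferon-inducible GTPase genes Iigp1, Irgm1 and Igtp rose by 1.92 ± 0.14, 1.66 ± 0.18 and 1.58 ± 0.11.

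T cell markers were lower in 9 of 12 at 6 h (10 adjusted over the list alone; median -0.48, adjusted p = 6.3e-06, and adjusted p = 0.124 with an estimated correlation). The costimulatory receptor gene Cd28 fell by 0.78 ± 0.12, Thy1 by 0.89 ± 0.21 and Cd3e, a chain of the T cell receptor complex, by 0.66 ± 0.16. The calls of Thy1 and Cd3e were lost without the arrays numbered 2, with fewer arrays at similar sizes (-0.83 and -0.66, adjusted p = 0.072 and 0.0828), and with the block and actin difference together (-0.63 and -0.38, adjusted p = 0.23 and 0.303). Of 51 markers of the other cell types 0 were called by limma, and 7 had an unadjusted p under 0.05. Among the 2 largest changes of each of these lists, the only ones looked up with the replicate block, limma called Mpeg1 (-0.46, adjusted p = 0.0048), Cd8b1 (-0.39, 0.0058), Cd74 (-0.39, 0.0086) and Crtam (-0.34, 0.0124) lower. The actin 3' to 5' difference was 0.86 with MAZ1310 and 1.07 with HF, higher with HF in 3 of 3 pairs. The exact permutation test, which does not use the pairs, gave p = 0.4 (two-sided). Naive T cell genes went both ways, 3 of 16 higher and 6 lower (adjusted p = 0.58). The homing receptor gene Ccr7 fell by 1.60 ± 0.19 and Bach2 by 1.01 ± 0.13, while Satb1, a chromatin organiser, rose by 0.76 ± 0.09.

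The Th17 list had 3 of 14 genes higher and 1 lower at 6 h (3 and 2 adjusted over the list alone; adjusted p = 0.21), with Batf at 0.75 ± 0.10 and Maf, a Th17 and Tfh transcription factor gene, at -0.89 ± 0.17. Il17a differed by 0.17 ± 0.34 (95% interval -0.54 to 0.89, adjusted p = 0.81), with HF higher in 3 of 3 pairs by 0.10 to 0.24 and a blocked interval of -0.12 to 0.46 (adjusted p = 0.46). The intervals were -0.58 to 0.23 for Rora, -0.13 to 0.31 for Il2 and -0.25 to 0.19 for Smad7. Il2 read 18606 to 20953 units on the 6 h arrays, near the array maxima of 23875 to 24343, where a difference can be compressed. The Th1 list had 2 of 12 higher and 1 lower (3 and 2 adjusted over the list alone; adjusted p = 0.16), with Tbx21 at 1.39 ± 0.11 and the IL-12 receptor gene Il12rb2 at 1.02 ± 0.18. The Th2 and Treg lists each had 1 gene higher, Nfil3 (0.64 ± 0.13) and Ikzf4 (0.74 ± 0.09), with adjusted p = 0.716 and 0.888, and TGFb response genes were higher in 2 of 18 and lower in 3 (adjusted p = 0.99). Glycolysis and hypoxia genes were higher in 4 of 17 and lower in 4 (4 and 5 adjusted over the list alone; adjusted p = 0.91), with Vegfa at 2.54 ± 0.09 and Tpi1 at -1.17 ± 0.11. NRF2 targets were lower in 4 of 14 (2 higher and 4 lower adjusted over the list alone; adjusted p = 0.58).

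Ribosome biogenesis genes shifted upward at 6 h as a list with 1 of 25 called (median 0.14, adjusted p = 0.0028, and adjusted p = 0.581 with an estimated correlation), a call lost with the replicate block and the actin difference together (adjusted p = 0.11). Ribosomal protein genes had 0 of 23 called by limma and 1 at an unadjusted p under 0.05 (adjusted p = 0.72). Autophagy and lysosome genes were lower in 4 of 19 (5 adjusted over the list alone; adjusted p = 0.045, and adjusted p = 0.258 with an estimated correlation), with the cathepsin gene Ctsb at -0.96 ± 0.10. The autophagy call was lost without HF replicate 2 or MAZ1310 replicate 1 or 2 at 6 h, or any MAZ1310 array at 3 h (adjusted p 0.051 to 0.12). The mTORC1 list had 2 of 15 genes higher and 3 lower (adjusted p = 0.911). Translation factors were higher in 2 of 21 and lower in 3 (3 and 3 adjusted over the list alone, adjusted p = 0.911). Genes of the eIF2a kinases and phosphatases were higher in 2 of 9 and lower in 2 (2 and 3 adjusted over the list alone, adjusted p = 0.989). Median, mean and test differed in sign for the Treg, glycolysis, mTORC1, eIF2a kinase and CD8 or NK lists at 6 h. With the replicate block and the actin difference in the fit together 910 genes differed at 6 h, and 1737 did without the 4 arrays numbered 2.

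The genes that differed at both times in the same direction were counted next. There were 1099, 312 higher and 787 lower, where independent lists would share 26.8 and 142. With at least a 2-fold change at both times there were 66, 47 higher and 19 lower, where independent lists would share 0.338 and 0.409. By mean size the leading genes were Gpt2, Trib3, Chac1, Eif4ebp1, Pck2, Cth (1.10 ± 0.20 and 4.01 ± 0.20), Cebpb, Ddit3, Atf5 (1.23 ± 0.16 and 3.14 ± 0.16) and Gbp7 (1.22 ± 0.19 and 3.08 ± 0.19). Of the genes higher at 3 h, 60.7% were also called higher at 6 h, and of those lower, 64.9% were also called lower. Across genes, which are not independent replicates, the HF effects at 3 h and 6 h correlated at r = 0.66, and 1599 of the 1726 genes called at 3 h kept their sign (92.6%). The comparisons use separate arrays, but equal replicate numbers tie them, and 12 genes were called in opposite directions. With the replicate block alone the count was 1506. With the block and the actin difference together it was 226, and without the arrays numbered 2 it was 394.

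**Figure D3:**
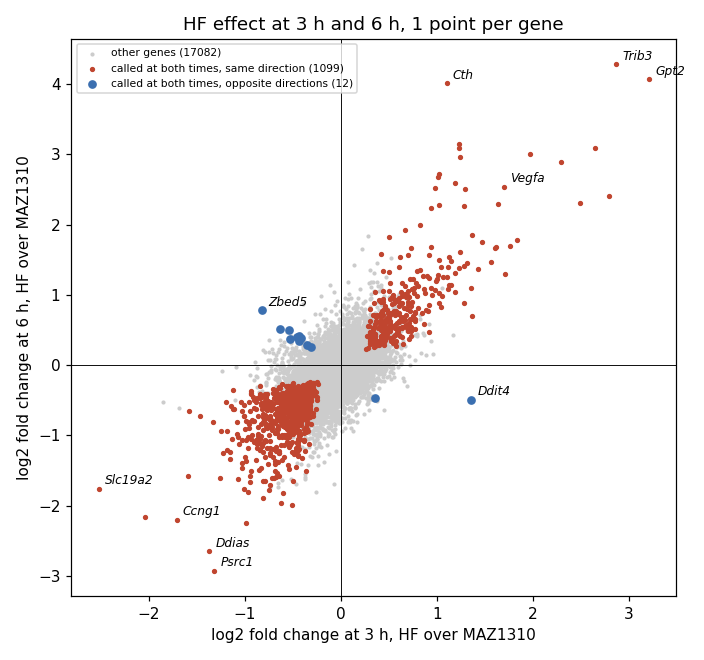
Log2 fold change of HF over MAZ1310 at 3 h (horizontal axis) and 6 h (vertical axis), with 1 point per gene, for 1099 genes called at both times in the same direction, 12 called in opposite directions and the others. Gpt2 and Trib3 lie at the upper right, Cth rises from 1.10 to 4.01, and Ddit4 lies at 1.35 and -0.50.

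Whether the HF effect differed between the times was tested as the difference of the log2 fold changes, 6 h minus 3 h. Cth gained 2.91 ± 0.28 (adjusted p = 2.0e-04), Atf5 1.91 ± 0.22, Gbp7 1.86 ± 0.27, Gbp8 1.73 ± 0.29, Slc14a1 1.69 ± 0.23 and Slc7a3 1.66 ± 0.24. In the other direction stood Ddit4, an inhibitor of mTORC1, with -1.85 ± 0.16 (adjusted p = 1.4e-04). Its effect went from 1.35 ± 0.11 at 3 h to -0.50 ± 0.11 at 6 h. The MAZ1310 arrays of Ddit4 read 446 to 646 units at 3 h and 1637 to 1783 at 6 h. The HF arrays read 1265 to 1406 and 1146 to 1248, so the change of sign came mainly with the rise under MAZ1310. Ier3, an immediate early gene (-1.62 ± 0.18), Psrc1 (-1.60 ± 0.29), Gpr174 (-1.55 ± 0.31) and Gcdh (-1.49 ± 0.19) followed. Laptm5 had -1.33 ± 0.18 on its brightest probe set, and 0.039 (adjusted p = 0.958) without suffixed probe sets.

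In all, the effect differed for 328 genes, 161 with a positive and 167 with a negative difference. With the replicate number as a block there were 680, among them Thy1 (-0.99, adjusted p = 0.0219), Nr4a1 (0.57, 0.017), Lta (-0.55, 0.0499) and Fdps (-0.54, 0.0405), and the Th1 list passed as well (adjusted p = 0.0412, against 0.0588 without the block). The count depended on single arrays. It was 602 without MAZ1310 replicate 1 at 3 h (386 positive and 216 negative), 129 and 180 without HF replicates 1 and 3 at 3 h, 141 and 172 without MAZ1310 replicates 2 and 3 at 6 h, and 136 and 170 without HF replicates 1 and 2 at 6 h. Without the 4 arrays numbered 2 it was 38, and with the block and the actin difference together 819.

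Of the lists, 15 passed camera for the difference of effects and 0 passed with an estimated correlation. For p53 targets the HF effect was more negative at 6 h than at 3 h (5 of 16 negative, 9 adjusted over the list alone, median -0.51, adjusted p = 1.8e-06, and adjusted p = 0.146 with an estimated correlation), with Phlda3 at -1.15 ± 0.16. Most p53 targets called over time rose under both compounds, as given below. The effect was more negative for T cell markers too (0 of 12 called by limma, 2 adjusted over the list alone, median -0.27, adjusted p = 0.00063, and adjusted p = 0.263 with an estimated correlation). It was more positive for the IL-6 and STAT3 list (3 of 15 positive, 7 positive and 1 negative adjusted over the list alone, median 0.38, adjusted p = 7.2e-06, and adjusted p = 0.0736 with an estimated correlation), with Il6st at 0.82 ± 0.13. The called genes of this list fell over time under both compounds, as given below. The interferon list also had a more positive effect (3 of 21, 4 adjusted over the list alone, median 0.16, adjusted p = 1.3e-05, and adjusted p = 0.334 with an estimated correlation), with Iigp1 at 1.25 ± 0.19, and its called genes likewise fell over time. Heat shock genes, lower at 3 h, had a positive difference in 3 of 14 (6 adjusted over the list alone, median 0.24, adjusted p = 4e-07, and adjusted p = 0.128 with an estimated correlation), with Hsph1 at 0.94 ± 0.16. Glycolysis and hypoxia genes had 3 of 17 positive (5 adjusted over the list alone; adjusted p = 6.5e-05, and adjusted p = 0.209 with an estimated correlation), with Vegfa at 0.84 ± 0.13.

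Amino acid synthesis enzymes had 2 of 20 positive (5 adjusted over the list alone; adjusted p = 1.3e-05, and adjusted p = 0.209 with an estimated correlation) and transporters 2 of 19 (6 adjusted over the list alone; adjusted p = 1.7e-05, and adjusted p = 0.0736 with an estimated correlation). The ATF4 list had 3 of 23 positive and 1 negative (5 and 1 adjusted over the list alone; adjusted p = 0.0022, and adjusted p = 0.0736 with an estimated correlation), with Cebpb at 1.04 ± 0.15. Its call was lost without suffixed probe sets (adjusted p = 0.066). Early T cell receptor genes (median 0.19, adjusted p = 0.002, and adjusted p = 0.189 with an estimated correlation) and ribosome biogenesis genes (median 0.20, adjusted p = 1e-05, and adjusted p = 0.334 with an estimated correlation) had more positive effects at 6 h, with 0 members called by limma, and with 1 and 0 adjusted over the list alone. The remaining lists were endoplasmic reticulum chaperones (2 positive and 2 negative of 20, 2 and 3 adjusted over the list alone, adjusted p = 0.03), sterol synthesis (0 of 18 called by limma, 5 negative adjusted over the list alone, 0.038), NRF2 targets (3 of 14 positive, 0.023) and translation factors (0 of 21 called, 0.023), with adjusted p = 0.334, 0.544, 0.418 and 0.571 with an estimated correlation.

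Those last 4 lists lost their calls without single arrays. The chaperone list did so without HF replicate 1 or 3 or MAZ1310 replicate 1 or 3 at 3 h, or MAZ1310 replicate 2 at 6 h (adjusted p 0.054 to 0.099). The sterol list did so without HF replicate 3 or MAZ1310 replicate 1 or 3 at 3 h, or HF replicate 1 or MAZ1310 replicate 1 or 2 at 6 h (0.051 to 0.33). The NRF2 list did so without HF replicate 2 or MAZ1310 replicate 3 at 3 h, or HF replicate 3 or MAZ1310 replicate 2 at 6 h (0.055 to 0.11), and the translation list without HF replicate 2 or MAZ1310 replicate 3 at 3 h (0.06 and 0.40). Median, mean and test differed in sign for the Th2, B cell, CD8 or NK and MHC class II lists.

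**Figure D4:**
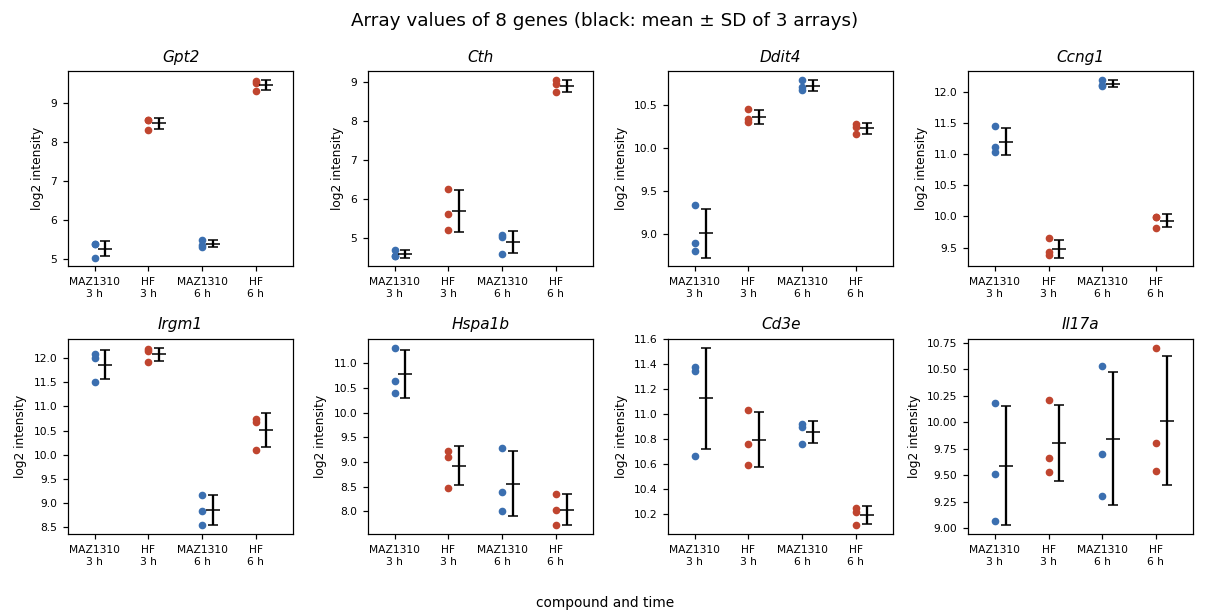
Log2 intensity of single arrays (points, vertical axis) for 8 genes in the 4 groups of compound and time (horizontal axis), with the mean ± SD of 3 arrays in black. Cth averaged 4.58 and 4.89 with MAZ1310 and 5.68 and 8.90 with HF, while the arrays of Il17a overlapped in the 4 groups.

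The change from 3 h to 6 h under MAZ1310 served as the reference course of culture. Cpd, a carboxypeptidase gene, rose by 3.09 ± 0.15 (adjusted p = 1.7e-08), the lymphotoxin gene Lta by 2.91 ± 0.15, Crabp2, a retinoic acid binding protein gene, by 2.34 ± 0.25, Pdgfb by 2.24 ± 0.35 and Gphn by 2.17 ± 0.16. Interferon-inducible genes fell, Gbp8 by 3.19 ± 0.20, Ifi213 by 3.14 ± 0.17, Gbp7 by 3.04 ± 0.19 and Irgm1 by 3.02 ± 0.18. Arhgap15, a Rac GTPase activating protein gene, fell by 3.10 ± 0.25 and Kbtbd11 by 3.09 ± 0.14. In all, 3595 genes changed, 2205 up and 1390 down.

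By list, interferon response genes fell in 19 of 21 (median -1.36, adjusted p = 1e-20, and adjusted p = 0.171 with an estimated correlation). IL-6 and STAT3 response genes fell in 11 of 15 (median -0.72, adjusted p = 6.3e-10, and adjusted p = 0.0435 with an estimated correlation), with Socs3 at -1.90 ± 0.16 and Il6st at -1.51 ± 0.09. Early T cell receptor genes fell in 14 of 29 and rose in 6 (15 and 6 adjusted over the list alone; adjusted p = 0.0066, and adjusted p = 0.353 with an estimated correlation), a call lost without suffixed probe sets (adjusted p = 0.062), with Egr3 at -1.41 ± 0.12. The p53 targets rose in 10 of 16 and fell in 1 (11 and 1 adjusted over the list alone, median 0.52, adjusted p = 3e-07, and adjusted p = 0.199 with an estimated correlation), with the cell cycle inhibitor gene Cdkn1a at 1.36 ± 0.10. Th1 genes fell in 4 of 12 (5 lower and 1 higher adjusted over the list alone; adjusted p = 0.0047, and adjusted p = 0.485 with an estimated correlation), with Tbx21 at -1.23 ± 0.11. Amino acid synthesis enzymes rose in 8 of 20 and fell in 1 (adjusted p = 0.013, and adjusted p = 0.485 with an estimated correlation), with the branched-chain transaminase gene Bcat1 at 1.77 ± 0.11. That call was lost without MAZ1310 replicate 1 at 3 h (adjusted p = 0.10), without dim genes (0.0748) and without suffixed probe sets (0.22).

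Ribosomal protein genes rose in 3 of 23 (2 adjusted over the list alone; adjusted p = 0.0066, and adjusted p = 0.485 with an estimated correlation), with Rpl14 at 0.83 ± 0.12. That call was lost without MAZ1310 replicate 3 at 3 h (adjusted p = 0.057) and with the block and the actin difference together (0.33). MHC class II presenting cell genes had 1 of 9 lower (adjusted p = 0.014, and adjusted p = 0.485 with an estimated correlation), lost without MAZ1310 replicate 1 at 3 h (0.10) or replicate 2 at 6 h (0.065). Median, mean and test differed in sign for the Treg, cell cycle, ribosome biogenesis, autophagy and translation lists.

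Under HF the change from 3 h to 6 h covered 2838 genes, 1516 up and 1322 down. The majority turned after cyclic loess (1394 up and 1529 down) and with the block and the actin difference together (806 and 929). Cth rose by 3.22 ± 0.20 (adjusted p = 2e-07), Pdgfb by 2.44 ± 0.35, Gphn by 2.40 ± 0.16, Lta by 2.37 ± 0.15 and Timp1, a metalloproteinase inhibitor gene, by 2.33 ± 0.32. Arhgap15 fell by 3.05 ± 0.25, Kbtbd11 by 2.43 ± 0.14, and the interferon-inducible genes Samd9l, Rtp4 and Epsti1 by 2.64 ± 0.17, 2.59 ± 0.25 and 2.36 ± 0.21.

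By list under HF, interferon response genes fell in 18 of 21 (median -0.99, adjusted p = 1.1e-15, and adjusted p = 0.165 with an estimated correlation). Amino acid synthesis enzymes rose in 11 of 20 (14 adjusted over the list alone, median 0.47, adjusted p = 1.2e-10, and adjusted p = 0.11 with an estimated correlation), with Asns at 1.42 ± 0.17. T cell markers fell in 8 of 12 and rose in 2 (9 and 2 adjusted over the list alone, median -0.63, adjusted p = 0.00075, and adjusted p = 0.308 with an estimated correlation), with Cd28 at -1.12 ± 0.12. TGFb response genes rose in 6 of 18 and fell in 1 (8 and 1 adjusted over the list alone; adjusted p = 0.0015, and adjusted p = 0.11 with an estimated correlation), with Klf10 at 2.02 ± 0.23. IL-6 and STAT3 genes fell in 7 of 15 (9 adjusted over the list alone; adjusted p = 4.6e-05, and adjusted p = 0.11 with an estimated correlation), with Il6ra at -2.31 ± 0.17. Glycolysis and hypoxia genes rose in 8 of 17 and fell in 2 (adjusted p = 0.00075, and adjusted p = 0.308 with an estimated correlation), with the oxygen sensor gene Egln3 at 1.81 ± 0.21. Naive T cell genes fell in 6 of 16 and rose in 1 (9 and 2 adjusted over the list alone; adjusted p = 0.0093, and adjusted p = 0.308 with an estimated correlation), with the IL-7 receptor gene Il7r at -1.34 ± 0.15. The naive T cell call was lost without dim genes (adjusted p = 0.051).

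Of the other lists under HF, ribosome biogenesis genes rose in 4 of 25 (6 adjusted over the list alone; adjusted p = 0.00087, and adjusted p = 0.522 with an estimated correlation), a call lost after cyclic loess (0.068). Amino acid transporters rose in 4 of 19 (adjusted p = 0.043), heat shock genes rose in 6 of 14 and fell in 1 (8 and 2 adjusted over the list alone; 0.023), p53 targets rose in 6 of 16 and fell in 1 (0.024) and translation factors rose in 2 of 21 (0.035). Th1 genes fell in 5 of 12 and rose in 1 (7 and 1 adjusted over the list alone; adjusted p = 0.04), and MHC class II presenting cell genes fell in 1 of 9 (5 lower and 1 higher adjusted over the list alone; 0.024). With an estimated correlation these 6 lists had adjusted p = 0.308 for transporters, 0.517 for heat shock, 0.517 for p53, 0.566 for translation, 0.538 for Th1 and 0.538 for MHC class II. The calls of transporters, heat shock, p53, translation and MHC class II were lost after cyclic loess, as was that of Th1, and single arrays ended each. These arrays were HF replicate 2 at 3 h for heat shock and p53 (0.052 each), and HF replicate 2 at 3 h or HF replicate 1 at 6 h for translation (0.094 and 0.066). For transporters they were HF replicate 1 or 2 or MAZ1310 replicate 3 at 3 h, or HF replicate 2 at 6 h (0.052 to 0.087). For Th1 they were HF replicate 1 or MAZ1310 replicate 3 at 3 h, or HF replicate 2 or 3 at 6 h (0.052 to 0.14), and for MHC class II HF replicate 1 at 3 h or replicate 2 at 6 h (0.13 and 0.072). Median, mean and test of the mTORC1 list differed in sign.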

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

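Tests chosen only after the results were seen were the 3 tests of why more genes were lower than higher, the share of the course missing with HF, the splits within replicate numbers, both tests on T cell markers and the fits with the actin difference or without the arrays numbered 2. The differences of Il17a within pairs and its blocked intervals were also chosen after its values were seen.

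The HF effect differed between 3 h and 6 h for 328 genes by the test of the difference itself, which 1 of 100 drawn splits reached, the real one, and the highest other gave 24. Among 100 splits that exchange arrays only within a replicate number, 1 reached 328 without the block, the real one, and the highest other gave 0. Of 100 such splits with the replicate block, 2 reached 680, as another gave 1099, which exchanges the sides of MAZ1310 replicate 1 at 3 h and 6 h; why it calls more was not tested. The count itself ran from 38 without the arrays numbered 2 to 819 with the block and the actin difference. Named genes with a larger effect at 6 h, in log2 units, were Cth (2.91), Atf5 (1.91), Gbp7 (1.86), Gbp8 (1.73), Slc14a1 (1.69), Slc7a3 (1.66), Trib3 (1.41), Slc6a9 (1.22), Cebpb (1.04) and Gpt2 (0.86). Those of the interferon, IL-6 and hypoxia lists were Irgm1 (1.44), Iigp1 (1.25), Igtp (1.16), Socs3 (0.92), Il6st (0.82), Stat3 (0.59), Hk2 (1.00), Vegfa (0.84) and Pfkp (0.68). Positive differences also stood for the NRF2, heat shock and chaperone genes Txnrd1 (0.94), Gclc (0.87), Hmox1 (0.84), Hsph1 (0.94), Dnajb1 (0.55), Hspa8 (0.47), Dnajb9 (0.62) and Atf6 (0.61). Negative differences stood for Ddit4 (-1.85), Ier3 (-1.62), Psrc1 (-1.60), Gpr174 (-1.55), Gcdh (-1.49), Laptm5 (-1.33), Pdia3 (-0.85), Pdia4 (-0.71), Phlda3 (-1.15), Plk2 (-0.99), Ei24 (-0.84) and Polk (-0.75). Single arrays ended the calls of Atf6, Dnajb1, Dnajb9, Gpr174, Hk2, Hmox1, Hspa8, Pdia4, Pfkp, Polk, Socs3, Stat3, Trib3 and Txnrd1.

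Lists whose HF effect differed between the times with the preset correlation, of which 0 passed with an estimated one (adjusted p 0.0736 to 0.571), had these median differences: ATF4 targets 0.11, amino acid synthesis 0.22, amino acid transport 0.087, IL-6 and STAT3 0.38, T cell receptor 0.19, ribosome biogenesis 0.20, glycolysis and hypoxia 0.23, NRF2 0.10, heat shock 0.24, interferon 0.16 and translation factors 0.12. Negative medians stood for endoplasmic reticulum chaperones (-0.22), sterol synthesis (-0.18), p53 targets (-0.51) and T cell markers (-0.27). Among 10092 probe sets without a single gene name, which no comparison used, limma called 168 at 3 h (79 higher and 89 lower) and 339 at 6 h (176 higher and 163 lower). Lower calls were in excess at 3 h only, and by a smaller share than among named genes.

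The counts of called genes at 3 h (1726, and 96 at 2-fold), at 6 h (3085 and 291) and over time (3595 with MAZ1310, 2838 with HF) were the highest of the 10 splits of their 6 arrays, and the highest other gave 0 in each. Only 1 of 10 splits gave as many, and 10 splits are too few for a share under 0.05. Among the 4 splits that part 3 replicate pairs the highest other also gave 0. For the genes called at both times, 1099 and 66 at 2-fold were reached in 1 of 100 drawn splits, the real one, and the highest other was 0. These draws did not keep to the replicate numbers that tie the arrays, so they cannot exclude chance for paired arrays.

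More genes were lower than higher with HF at both times. At 2-fold this held at 6 h (177 lower and 114 higher), but not at 3 h (42 lower and 54 higher). It also did not hold at 2-fold for genes called at both times (19 lower and 47 higher). The lower of the medians over all genes was 0.0233, but normalization to equal distributions fixes such medians near 0, so a constant offset of the HF arrays, or a shift of all transcripts, stays open. Normalization that depends on intensity does not account for the whole pattern, since after cyclic loess between arrays at least 57.1% of calls were still lower over both times and each array left out, against 70.2% and 69.2% as deposited. With the replicate block and the actin difference in the fit, calls fell to 419 and 910 as the standard error grew: genes called lower went from a median of -0.48 to -0.47 at 3 h (median SE 0.104 to 0.166) and from -0.51 to -0.44 at 6 h (0.104 to 0.155), at least 85.1% of the change in each fit. These genes thus kept most of their change beside the actin difference. HF had the higher actin difference in 3 of 3 pairs at both times, so these fits cannot fully part RNA quality from HF. The excess of lower calls shrank with the block and the actin difference to 234 against 185 at 3 h and 583 against 327 at 6 h. It was 113 against 113 for genes called at both times, so how far the excess of calls depends on array quality stays open.

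The HF effect at 6 h opposed the change from 3 h to 6 h under MAZ1310. Of 2205 genes that rose over time, 1139 were lower and 47 higher with HF at 6 h (259 and 115 expected of independent lists), and of 1390 that fell, 90 were lower and 474 higher (163 and 72.5 expected). Both changes share the MAZ1310 6 h arrays, which alone gave rank correlations of -0.480 to -0.457 in simulations without effects, close to the observed -0.516, and a covariance of -0.00747 against the observed -0.0586. On arrays and replicate numbers that share nothing the rank correlations across genes were -0.368, -0.398 and -0.250, the last the highest. With the actin slope removed the highest was -0.287. The simulations gave -0.0181 to 0.0176 on such arrays, but they drew the noise of each gene independently. On real arrays genes can deviate together, so that range may be too narrow and cannot exclude chance. On separate arrays, genes were picked by a change of at least 2-fold over time under MAZ1310 on 1 replicate number. On the other numbers at least 31.3% of their median change was missing at 6 h with HF, in 3 rotations and both directions. The arrays that picked the genes also gave the size of that change, so the share can be understated. This share restates the opposition as a size, and whether HF holds back the change over time stays open.

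T cell marker genes were lower with HF at 6 h, with a list median of -0.48 (camera adjusted p = 6.3e-06, but adjusted p = 0.124 with an estimated correlation). A lower share of T cells could raise markers of some other cell type, by a size that depends on the mix of cells and is not known here. The highest median among those 5 lists was 0.0749, in B cell genes, and 0 of 51 such markers were called by limma, with 7 at an unadjusted p under 0.05. Of the markers looked up with the replicate block, limma called Mpeg1, Cd8b1, Cd74 and Crtam lower. The test is limited by dim markers, since the median log2 intensity with MAZ1310 was 11.5 for T cell markers and 6.20 to 7.14 for the other lists. It therefore cannot decide whether the share of T cells differed. RNA quality cannot be told apart from HF here: the median kept 96.0% of its size with the actin difference in the fit and 50.1% with the replicate block as well, and HF had the higher difference in every pair. An effect of HF on these transcripts may be part or all of the pattern, and was not tested further.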

How the results depend on the processing

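Tests with the actin difference or without the arrays numbered 2 were chosen after the data were seen, and the others were planned. Signal over background limits dim genes in all of them. More tested probe sets, fewer arrays or a stricter threshold move counts by construction, and for the other changes the cause was not tested. With every probe set on its own the counts were 174 (3 h, 2-fold), 4674 (6 h), 500 (6 h, 2-fold), 118 (both times, 2-fold), 5705 (over time, MAZ1310) and 4452 (over time, HF). Array weights gave 4712 at 6 h and 690 for the difference of effects, with a lowest weight of 0.302 for MAZ1310 replicate 3 at 3 h. The compared groups alone gave 894 at 3 h and 715 at both times. The replicate block gave 680 for the difference of effects and moved no other count by over 1.5 times. It gave 2428 at 3 h, 3714 at 6 h, 1506 at both times, 4254 for MAZ1310 over time and 3457 for HF over time. An adjusted p under 0.01 gave 854, 1991, 553, 74 and 1793 for 3 h, 6 h, both times, the difference and HF over time. Without the arrays numbered 2 these were 657, 1737, 394, 38 and 1806. The block with the actin difference gave 419, 910, 226, 819 and 1735, and 1883 for MAZ1310 over time. Without single arrays the ranges were 1223 to 2196 (3 h), 2288 to 3685 (6 h), 795 to 1183 (both), 129 to 602 (difference), 2858 to 3592 (MAZ1310) and 2043 to 3459 (HF), and at 2-fold 92 to 124, 283 to 318 and 62 to 75. Without suffixed probe sets Eif2ak4 turned from -0.46 to 0.20 at 3 h (adjusted p = 0.434), and Laptm5 to 0.20 at 6 h (0.11) and 0.039 for the difference (0.958), where another probe set stands for the gene. Of 384 values of named genes, 371 kept their side of the threshold with the block and 13 gained a call, 73 lost one without the arrays numbered 2 and 81 with the block and the actin difference. The gains are given with their results, and the block changed no other call of a named gene. Losses without the arrays numbered 2 or with the block and actin difference stand beside the gene only for Atf4, Thy1 and Cd3e. Of 160 list tests, 1 gained a call with the block and 53 lost a call with an estimated correlation. With fry 17 lost a call and 11 gained one. Cyclic loess moved the split of calls from 514 higher and 1212 lower to 723 and 1085 at 3 h.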

Other observations

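The tests on gene families were chosen after the data were seen. Genes were grouped by the letters that start their symbols, which gave 295 families of at least 8 measured genes. Transcripts of mitochondrial ribosomal proteins stood out in the course of culture: of 47 Mrpl genes 43 rose from 3 h to 6 h under MAZ1310 (median 0.61, camera adjusted p = 2.1e-23, but 0.566 with an estimated correlation) and 18 rose and 1 fell under HF (median 0.29, adjusted p = 2.1e-08, but 0.975). Of 29 Mrps genes 21 rose under MAZ1310 and 11 under HF. At 6 h, 25 Mrpl genes were lower with HF and 0 higher (median -0.33, adjusted p = 3.9e-09), as were 13 Mrps genes (median -0.39, adjusted p = 1.2e-05), but with an estimated correlation both had 0.851. Mrpl34 stood at -1.26 ± 0.15 and Mrpl18 at -0.96 ± 0.12. The difference of HF effects shifted the Mrpl family down (median -0.36, adjusted p = 1.1e-12, but 0.991 with an estimated correlation).

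Other families passed camera at 6 h with the preset correlation only. With an estimated one the adjusted p was 0.532 for the tubulin and Irf families and 0.851 for the Psmd, Commd and Gimap families. Of 14 Psmd genes, subunits of the 19S proteasome regulator and its cofactors, 7 were lower with HF (median -0.42, adjusted p = 1.2e-05), with Psmd13 at -0.83 ± 0.09. Of 9 beta tubulin genes 5 were lower (median -0.95, adjusted p = 0.0017), with Tubb6 at -1.57 ± 0.16 and Tubb5 at -1.36 ± 0.09. Of 10 Commd genes 8 were lower (median -0.43, adjusted p = 5.7e-06), with Commd3 at -1.23 ± 0.11. Among 11 genes whose symbols start with Irf, which include Irf2 binding protein genes, 8 were higher (median 0.43, adjusted p = 0.00048), with Irf1 at 1.40 ± 0.11 and Irf2 at 0.98 ± 0.17. Of 8 Gimap genes, GTPases of lymphocyte survival, 4 were higher with HF at 6 h (median 0.30, adjusted p = 0.011), while all 8 fell over time under MAZ1310 (adjusted p = 2.5e-10, and 0.0913 with an estimated correlation) and under HF (median -0.76, adjusted p = 9.1e-09, and 0.129).

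Among the 12 genes called in opposite directions at 3 h and 6 h, chosen here after their values were seen, the HF effect went from 1.35 to -0.50 for Ddit4 and from 0.35 to -0.46 for Zbtb4. For Ddit4 this came mainly with its rise under MAZ1310, as given above. The other 10 were lower at 3 h and higher at 6 h, among them Zbed5 (-0.82 and 0.78), Fnip2 (-0.64 and 0.51) and Hs3st3b1 (-0.54 and 0.50).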
